A study of Gallus gallus with 8 samples.

How the data were processed

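RNA was measured on 8 Affymetrix chicken arrays carrying chondrocytes of the chick tibiotarsus growth plate, 4 arrays of proliferative and 4 of hypertrophic cells. Per the labels' protocols, the cells were isolated and pooled, RNA was purified with a column kit after lysis, and biotin-labelled target was made with the manufacturer's one-cycle kit. The deposited table holds log2 values that were made by RMA, per the submitters' processing notes. RMA corrects background, quantile-normalises the arrays together and summarises each probe set, so deposited values lie between 2.52 and 14.7 and arrays have nearly equal medians. It also compresses differences among dim probe sets. The RMA software and its version are not given in the sources used here. Arrays have no sequencing depth, and their number limits the precision.

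The hypertrophic cells came from chicks 1 day old and the proliferative cells from chicks 3 weeks old, per the labels' protocols. Cell stage and age therefore differ together in every comparison and cannot be told apart. Nothing in the labels says that the arrays of a group come from separate birds or separate pools, so p-values measure only the spread between these samples, which may be technical.

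The table has 38535 rows. The 96 control probe sets were left out of the tests, which left 38439. Through the platform annotation, with symbols updated by gene identifier from the RefSeq gene table of assembly GRCg7b, 27168 probe sets have 1 gene symbol, 177 have several and 11094 have none. Symbols of 26863 probe sets came from the RefSeq table. No gene was named from a probe set with several symbols. The 13009 genes are each represented by the probe set with the highest mean over the 8 arrays, and 7334 of them have more than 1 probe set. As a background level, the 95th percentile of 742 probe sets for viral and reporter sequences was taken on each array, and its highest value, 4.72, was used. Both group means of 3043 genes lie below it, and 45 of these passed the test. Where only 1 group mean lies below it, a bound is given as the difference between the group means with each array of the dimmer group set to at least this level. Such a bound, worded as at least, concerns the estimate only. It leaves out sampling error and is not a confidence limit.

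Differences are hypertrophic minus proliferative, on the log2 scale. They were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over the 38439 probe sets and a threshold of 0.05. The error after a log2 difference is the standard error of that fit, with n = 4 arrays per group. The size limit of 2-fold is a limit on the estimate, not a test. Gene lists were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the 37 lists with at least 5 measured members. Controls of RNA quality were compared by an exact permutation test, two-sided, whose smallest possible p is 0.0286. The test was checked on simulated data of 38439 probe sets with 200 changed, 50 at each size. It recovered 70% of changes of 1 on the log2 scale, 94% of those of 2, and 100% of those of 3 or 4, with 9 false calls among 191. The simulated arrays were drawn independently, with no near-identical arrays and no link between probe sets. These rates therefore need not hold for the real arrays.

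The group of each array, the test, the 38 gene lists, the alternatives and the rule for named genes were fixed before the data were examined. The rule takes the 12 largest rises and the 12 largest falls among genes past the threshold whose groups do not overlap, leaving out placeholder symbols; 1 of these genes is not reported here. It adds up to 4 members per list with the largest change among those past the threshold, or up to 2 with the smallest p where none passed, and a set of growth plate, proliferation and blood genes chosen in advance. Genes that stood out on 1 array, or whose direction turned under an alternative, are named as well. Other members past the threshold are named in places to describe a list. PTH1R and CDKN1C of the set chosen in advance had no probe set with that symbol alone and were not analysed here. A list of Z-linked genes was written later from background knowledge and kept where assembly GRCg7b places the gene on that chromosome.

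Alternatives covered a filter on dim probe sets, 3 further normalisations, the variance model, array weights, a block for the replicate number, the omission of each array, a test against a minimum change, the probe set that represents a gene, an estimated inter-gene correlation and the rotation test fry. Further alternatives were chosen after seeing the data, because arrays 3 and 4 of each group were nearly identical. They average arrays 3 and 4 into 1 sample per group, treat arrays 1 and 2 against 3 and 4 as a block, use arrays 1 and 2 or arrays 3 and 4 alone, or use only proliferative arrays 1 and 2.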

Results

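Gene expression was measured in chondrocytes from the growth plate of the chick tibiotarsus, the main long bone of the lower leg. Proliferative chondrocytes divide in columns and lay down cartilage matrix. Hypertrophic chondrocytes have left the cell cycle, enlarged, and mineralise the matrix ahead of bone. There were 4 arrays of proliferative cells from 3-week-old chicks and 4 of hypertrophic cells from 1-day-old chicks. The comparison asks which transcripts differ between the 2 stages, in samples whose ages differ as well.

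The first principal component held 51.0% of the variance and separated the groups, with scores from -53.6 to -44.5 on proliferative arrays and from 6.93 to 77.0 on hypertrophic arrays. Hypertrophic array 1 had the score closest to the proliferative group. The second component, with 24.5% of the variance, set arrays 1 and 2 of each group above arrays 3 and 4. Arrays 3 and 4 were nearly identical within each group. Over 5344 bright probe sets the SD of their difference was 0.175 in proliferative and 0.194 in hypertrophic cells, against 0.365 to 0.958 for the other pairs within a group. Differences between arrays 3 and 4 were shared by separate probe sets of a gene at r = 0.173 and 0.209 over 318 genes, with permutation p = 0.0011 and 2e-04, against 0.480 to 0.775 for the other pairs within a group. All 8 arrays were kept as separate samples because the design was fixed before the data were examined, and the values do not show that arrays 3 and 4 are independent. Counts of genes and of list members are also given with arrays 3 and 4 averaged into 1 sample per group, a setting chosen after seeing the data.

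**Figure D1:**
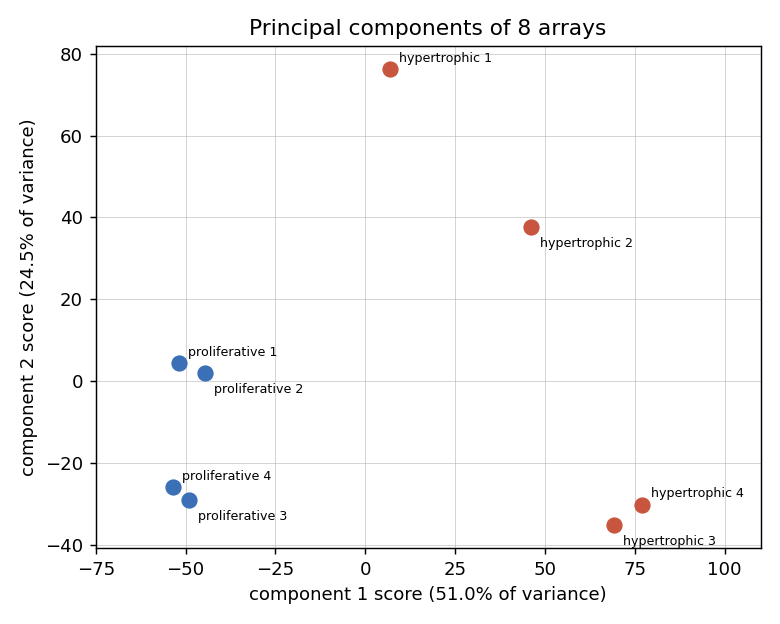
Scores of the 8 arrays on the first component (horizontal, 51.0% of variance) and the second component (vertical, 24.5%), with proliferative arrays in blue and hypertrophic arrays in red. Proliferative arrays lie at -44.5 or below on the first component and hypertrophic arrays at 6.93 or above, and arrays 3 and 4 of each group lie next to each other.

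Hypertrophic chondrocytes expressed 955 genes at a higher and 728 at a lower level than proliferative chondrocytes, of 13009 genes. With the arrays centred on ribosomal proteins the balance turned, to 898 genes higher and 958 lower. Ribosomal protein genes themselves had a median log2 difference of 0.13, and that centring subtracts their mean difference from every gene. Of the 1683 genes, 216 had 1 group mean below the background level of 4.72, so their differences are not measured on both sides, and a bound against that level is given for those named. That bound concerns the estimate and leaves out sampling error, so the true difference may be smaller. Among genes with both means above it, by the probe set that represents each gene, the largest rise was in EFEMP1, an extracellular matrix glycoprotein, at 5.44 ± 0.47 (log2 difference ± SE, n = 4 per group; adjusted p = 5.29e-04). PLA2R1, PPDPF, LOX and CLDN1 rose by 4.56, 4.37, 4.36 and 4.30. Proliferative means of KCNK2, PTN, SLC38A4, NELL2, AKR1D1 and TNFSF10 lay below background. KCNK2, a potassium channel of the 2-pore family, rose by at least 4.75 (estimate 5.77 ± 0.83, adjusted p = 0.00445), and PTN, the heparin-binding growth factor pleiotrophin, by at least 4.51 (estimate 5.56 ± 0.19, adjusted p = 5.51e-06). The amino acid transporter SLC38A4, NELL2, the steroid reductase AKR1D1 and TNFSF10 rose by at least 3.86, 4.15, 4.72 and 3.89, with estimates of 5.33 ± 1.01, 5.06 ± 0.37, 5.002 ± 0.32 and 4.48. The smallest adjusted p of all genes named here, 5.27e-07, was that of PPDPF.

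Falls were smaller. The chemokine CCL17 fell by 2.82 ± 0.23 on the log2 scale (adjusted p = 4.78e-04), the glutathione transferase GSTA4 fell by 2.68 ± 0.33, the lipoprotein receptor LRP8 fell by 2.47 ± 0.20 and the phosphodiesterase PDE4D fell by 2.33 ± 0.30. PAMR1, PROSER2, CDC45, DIAPH3, CKS2, HERPUD1, ADCY2 and DUSP10 followed, with log2 differences of -2.31, -2.28, -2.26, -2.24, -2.23, -2.21, -2.11 and -2.10. Of the genes that differed, 545 were at least 2-fold higher and 319 at least 2-fold lower. With arrays 3 and 4 averaged, 261 genes were higher and 161 lower, all 422 among the 1683 of the 8 arrays, and 221 and 125 passed with at least 2-fold. KCNK2, SLC38A4, LOX, CLDN1, DIAPH3, HERPUD1 and DUSP10 did not pass then, with adjusted p = 0.0504, 0.105, 0.106, 0.0550, 0.0761, 0.0723 and 0.0799. When 1 array was left out, LOX, HERPUD1 and DUSP10 missed the threshold in 6, 3 and 5 of the 8 fits, with adjusted p up to 0.0650, 0.0667 and 0.0867. Without hypertrophic array 1, 1562 genes were higher and 941 lower, and without proliferative array 3, 301 were lower; without proliferative array 4, 484 were higher.

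By probe set, 1726 were higher and 1642 lower, and 8652 had an unadjusted p under 0.05. The 2 groups did not overlap in 15.2% of probe sets. Chance gives 2.86% if all 8 arrays are separate samples, which arrays 3 and 4 of a group may not be. The chance share is higher if they are not. Probe sets of 6 genes passed in opposite directions (CSNK1G1, DIDO1, GPSM1, LMAN1L, TF and ZFHX4), which were named after their values were seen. In TF, the iron carrier transferrin, 1 pair of probe sets gave rises of 8.35 ± 0.62 and, with a proliferative mean below background, at least 8.40 (estimate 8.91 ± 0.37), while the probe set that represents the gene fell by 0.55 ± 0.12. Hypertrophic means of that pair were 13.9 and 13.1, against 5.53 and 4.22 in proliferative cells. Of KCNK2, 2 further probe sets passed, with rises of at least 2.69 and 1.90 (estimates 2.80 ± 0.67 and 2.93 ± 0.67). Of TNFSF10, a probe set nearly as bright as the representing one differed by 1.20 ± 0.44 and did not pass (adjusted p = 0.135). A dimmer one passed (estimate 2.26 ± 0.40), and its remaining probe sets did not.

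Markers of late growth plate stages passed as a list in camera at the preset correlation, higher (adjusted p = 0.00769), but not with an estimated correlation (adjusted p = 0.499). Among 34 measured hypertrophic and prehypertrophic markers, 8 rose, 1 fell and 25 did not pass; adjusted over the list alone, 12 rose and 3 fell. The collagenase MMP13 rose by 3.81 ± 1.00 (adjusted p = 0.0483), the pyrophosphate transporter ANKH by 3.55 ± 0.63, the bone phosphoglycoprotein MEPE by 3.49 ± 0.22, the gelatinase MMP9 by 3.41 ± 0.75 and osteopontin, SPP1, by 2.77 ± 0.34. Collagen X, COL10A1, was abundant in both groups, at 14.1 ± 0.29 in hypertrophic and 13.4 ± 1.0 in proliferative cells (mean ± SD, n = 4), a difference of 0.66 ± 0.43 that did not pass (adjusted p = 0.444). The hypertrophic means of COL10A1 and SPP1, both 14.1, lie close to the highest deposited value, 14.7, which limits the differences that can be read there. Differences in IHH, RUNX2, ALPL and VEGFA were -0.43 ± 0.29, 0.42 ± 0.33, 0.28 ± 0.25 and 0.29 ± 0.34, none past the test, and bone sialoprotein, IBSP, differed by 2.62 ± 0.71 (adjusted p = 0.0539). With arrays 3 and 4 averaged, 2 markers of the list rose, MEPE and SPP1, and none fell. MMP13, ANKH and MMP9 had adjusted p = 0.124, 0.0845 and 0.0794 in that setting, and IBSP 0.138. MMP13 and MMP9 lost the call in 7 and 4 of the 8 fits that leave out 1 array (adjusted p up to 0.119 and 0.0690); IBSP passed without proliferative array 1 and without hypertrophic array 1 (adjusted p = 0.0383 and 0.0469), and with arrays 1 and 2 against arrays 3 and 4 as a block (adjusted p = 0.00878), which counts arrays 3 and 4 as separate samples. From 4 to 12 markers rose when 1 array was left out, the fewest without hypertrophic array 2, 3 or 4 and the most without hypertrophic array 1, and 0 to 2 fell.

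Mineralisation and phosphate handling passed camera in the same direction (adjusted p = 0.0153), but not with an estimated correlation (adjusted p = 0.499). Of its 26 measured genes 6 rose, 1 fell and 19 did not pass; adjusted over the list alone, 11 rose and 3 fell. Besides ANKH, MEPE and SPP1, which both lists hold, the secretory kinase FAM20C rose by 1.92 ± 0.37. MGP, an inhibitor of calcification, rose by 1.41, and the carbonic anhydrase CA12 had a difference of -1.43. With arrays 3 and 4 averaged, 4 of its genes rose, MEPE and SPP1 among them, while ANKH and FAM20C did not pass (adjusted p = 0.0845 and 0.0954). FAM20C also missed the threshold without proliferative array 4 (adjusted p = 0.0502), and 10 genes of the list rose without hypertrophic array 1. Some markers of other cell types were higher on the same arrays: the endothelial cadherin CDH5 by 3.06 ± 0.33 and the osteoclast proton pump subunit ATP6V0D2, whose proliferative mean lay below background, by at least 2.502 (estimate 2.88 ± 0.38). In those lists 21 of 27 endothelial and 11 of 15 osteoclast markers did not pass, and 1 osteoclast marker fell.

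**Figure D2:**
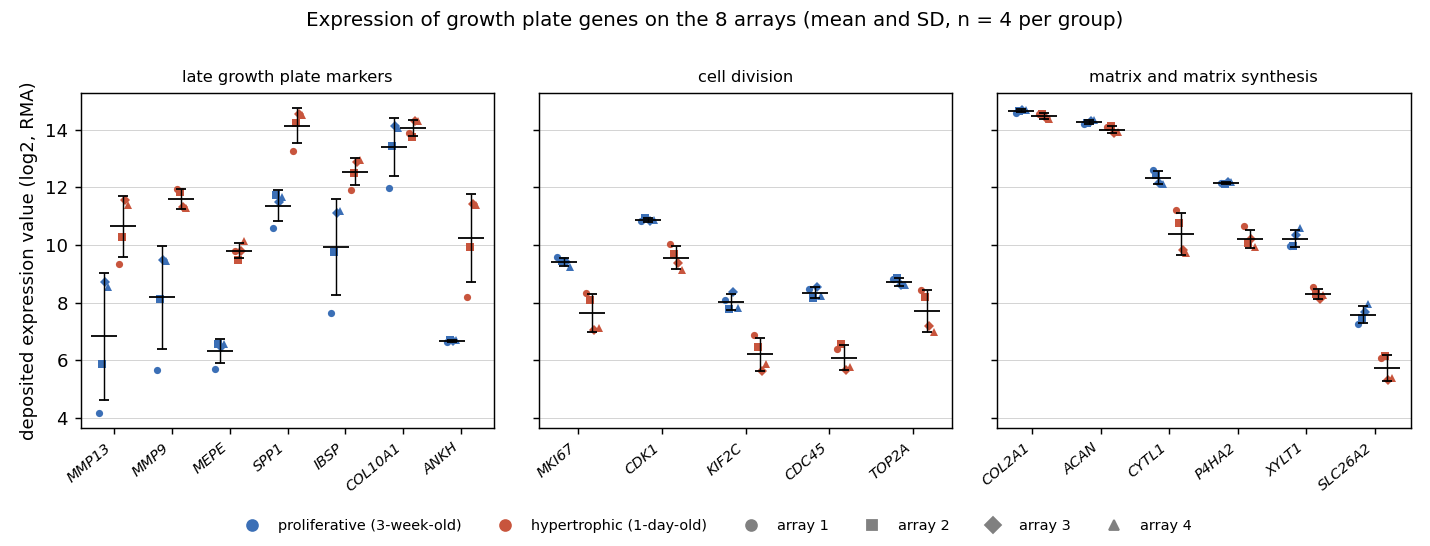
Deposited log2 expression values (vertical axis) of 18 growth plate genes on each array, with array numbers as marker shapes, proliferative arrays in blue, hypertrophic arrays in red, and bars for the mean and SD of 4 arrays. COL10A1 lies between 11.99 and 14.3 over both groups, while MEPE lies at 6.56 or below on proliferative and at 9.496 or above on hypertrophic arrays.

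Genes of G2 and mitosis were lower in hypertrophic cells, with a median of -1.30 and adjusted p = 6.43e-23 in camera, or adjusted p = 0.499 with an estimated correlation. Of 58 measured genes 39 fell, none rose and 19 did not pass; adjusted over the list alone, 49 fell and 1 rose. KIF2C, a microtubule-depolymerising kinesin, fell by 1.81 ± 0.27 (adjusted p = 0.00538), the kinetochore protein CENPN fell by 1.79 ± 0.28 and the proliferation marker MKI67 fell by 1.76 ± 0.28. The kinesin KIF18A was below background in hypertrophic cells, which bounds its difference at -0.80 or lower (estimate -1.77 ± 0.17). CDK1, the kinase that drives entry into mitosis, fell by 1.31 ± 0.19. TOP2A had a difference of -1.01 ± 0.31 that did not pass (adjusted p = 0.0834), while its second probe set fell by 1.64 ± 0.36 (adjusted p = 0.0247). With arrays 3 and 4 averaged, 10 of the 58 fell, among them KIF2C, KIF18A and CDK1, while CENPN, MKI67 and TOP2A had adjusted p = 0.0709, 0.0577 and 0.283. From 21 to 49 fell when 1 array was left out, the fewest without proliferative array 3 and the most without hypertrophic array 1; without proliferative array 1 or 4 or hypertrophic array 4 it was 23, 25 and 24. TOP2A passed without hypertrophic array 1 (adjusted p = 0.0166) and with arrays 1 and 2 against arrays 3 and 4 as a block (adjusted p = 0.0116).

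Of 41 measured genes of S phase and replication, 2 fell, the replication helicase factor CDC45 by 2.26 ± 0.21 on the log2 scale and UHRF1 by 0.76 ± 0.12, and 39 did not pass, with the same count of 2 when adjusted over the list alone. The S phase list missed the threshold (adjusted p = 0.103). Among 20 cell cycle inhibitors 2 rose and 3 fell (adjusted p = 0.859), and adjusted over the list alone 4 rose and 4 fell. CCNG2 rose by 1.87 ± 0.20, CDKN2A, below background in hypertrophic cells, had a bound of -0.83 (estimate -1.19 ± 0.24), and CDKN1A differed by 1.10 ± 0.31 (adjusted p = 0.0654). Without 1 array, S phase passed in 3 of the 8 fits, at the lowest without hypertrophic array 1 (adjusted p = 0.0197), where CDKN1A passed too (adjusted p = 0.0157), as it did with arrays 1 and 2 against arrays 3 and 4 as a block (adjusted p = 0.0177), and CDKN2A missed the threshold in 2 (adjusted p up to 0.0520). Averaging arrays 3 and 4 left 2 S phase genes lower, and 1 inhibitor higher and none lower, with CDKN2A and CDKN1A at adjusted p = 0.0798 and 0.265. When 1 array was left out 2 to 4 S phase genes fell, the most without hypertrophic array 1, and 1 to 3 inhibitors passed in each direction.

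Core cartilage collagens and aggrecan lay near the top of the scale in both groups. COL2A1 had means of 14.5 ± 0.10 in hypertrophic and 14.7 ± 0.049 in proliferative cells (SD, n = 4), and the differences of COL2A1, ACAN and COL9A1, which did not pass, were -0.19 ± 0.09, -0.27 ± 0.10 and -0.45 ± 0.12 (adjusted p = 0.292, 0.144 and 0.0518). These probe sets lie close to the highest deposited value, 14.7. A second bright probe set passed for COL2A1, which fell by 0.49 ± 0.11 (adjusted p = 0.0320), and for COL9A1, which fell by 0.84 ± 0.14 (adjusted p = 0.00854), with means over the 8 arrays of 14.1 and 13.3. Of 32 cartilage matrix genes 1 rose, 6 fell and 25 did not pass; adjusted over the list alone, 5 rose and 12 fell. CYTL1, a secreted protein of chondrocytes, fell by 1.95 ± 0.32, fibromodulin, FMOD, fell by 1.44 ± 0.32 and epiphycan, EPYC, fell by 1.08 ± 0.20, while the collagen VI chain COL6A3 rose by 1.05 ± 0.16. MATN1 differed by 1.15 ± 0.32 (adjusted p = 0.0627), its second probe set rose by 1.38 ± 0.35 (adjusted p = 0.0424), and the first passed without hypertrophic array 1 (adjusted p = 3.91e-04), as did COL9A1 (adjusted p = 0.0160). Both passed with arrays 1 and 2 against arrays 3 and 4 as a block (adjusted p = 0.0287 and 0.0425), but not with arrays 3 and 4 averaged (adjusted p = 0.254 and 0.270). The list passed camera (adjusted p = 0.0153), with adjusted p = 0.665 with an estimated correlation. The call was lost with arrays 3 and 4 averaged (adjusted p = 0.0743, 1 gene higher and 0 lower) and with arrays 1 and 2 alone (adjusted p = 0.796). CYTL1, FMOD and EPYC did not pass with averaged arrays (adjusted p = 0.0603, 0.150 and 0.0953). Without hypertrophic array 1, 3 genes rose and 10 fell, without hypertrophic array 2, 5 fell, and when any 1 of the others was left out 3 fell. FMOD missed the threshold in 6 of the 8 fits that leave out 1 array, with adjusted p up to 0.0835.

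Several enzymes that build and modify matrix molecules fell. In glycosaminoglycan synthesis and sulfation, 5 of 55 genes rose and 10 fell; adjusted over the list alone, 8 rose and 15 fell. XYLT1, which starts the chains, fell by 1.90 ± 0.16, the sulfate transporter SLC26A2 fell by 1.85 ± 0.23, and the chondroitin enzymes CHSY3 and CHST12 had differences of -1.62 ± 0.23 and -1.46 ± 0.18. The list's adjusted p = 0.00709, or adjusted p = 0.499 with an estimated correlation. In collagen processing and secretion, 2 of 43 genes rose and 12 fell; adjusted over the list alone, 2 rose and 20 fell. The collagen prolyl hydroxylase subunit P4HA2 fell by 1.93 ± 0.15 (adjusted p = 3.87e-04) and the lysyl hydroxylase PLOD1 fell by 1.19 ± 0.28, while the crosslinking oxidases LOX and LOXL1 rose, LOXL1 by 2.09 ± 0.16. That list's adjusted p = 3.04e-05, or adjusted p = 0.499 with an estimated correlation. Averaging arrays 3 and 4 left 2 genes higher and 5 lower in the former list, and 1 higher and 2 lower in the latter. With arrays 1 and 2 alone neither list passed (adjusted p = 0.211 and 0.0605). Leaving out 1 array gave 2 to 8 higher and 7 to 12 lower in the former, and 1 or 2 higher and 2 to 20 lower in the latter, in each case the most lower without hypertrophic array 1 and the fewest without proliferative array 3 or 4; the latter also had 2 lower without hypertrophic array 4, and 3 without proliferative array 1 or hypertrophic array 3. PLOD1 missed the threshold in 6 of the 8 fits that leave out 1 array (adjusted p up to 0.0922) and with averaged arrays (adjusted p = 0.16996), as did LOX (adjusted p = 0.106).

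Of 32 measured genes of the unfolded protein response, 14 fell and none rose, and adjusted over the list alone 17 fell. The membrane protein HERPUD1 fell by 2.21 ± 0.45, the stress sensor kinases EIF2AK3 and ERN1 fell by 2.02 ± 0.19 and by 1.03 ± 0.23, and the disulfide isomerase PDIA6 fell by 1.08 ± 0.15. The chaperones HSPA5 and HSP90B1 had differences of -0.92 ± 0.22 and -0.68 ± 0.12. The list's adjusted p = 1.59e-06, with adjusted p = 0.0516 with an estimated correlation. With arrays 3 and 4 averaged, 4 of its genes fell, EIF2AK3 and PDIA6 among them, while HERPUD1, ERN1, HSPA5 and HSP90B1 did not pass (adjusted p = 0.0723, 0.0716, 0.115 and 0.0859). From 6 to 14 fell when 1 array was left out, the fewest without proliferative array 3 or 4, and 8 without hypertrophic array 2. When 1 array was left out, ERN1 and HSPA5 missed the threshold in 5 and 6 of the 8 fits (adjusted p up to 0.0873 and 0.107).

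**Figure D3:**
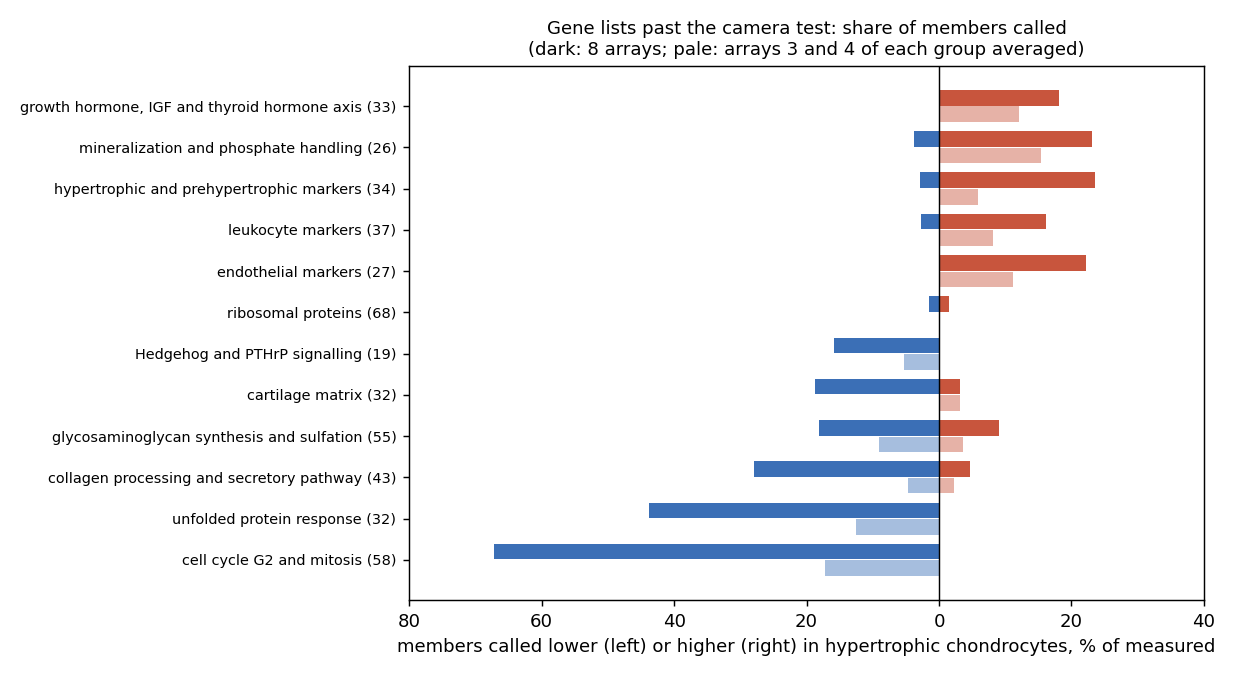
Members of each gene list past the camera test that were lower (blue, left) or higher (red, right) in hypertrophic chondrocytes, as a percentage of measured members (horizontal axis; number measured in brackets), with all 8 arrays (dark bars) and with arrays 3 and 4 of each group averaged (pale bars). The longest bar stands for 39 of 58 genes of G2 and mitosis, and 10 of 58 with averaged arrays.

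Hormone and growth factor genes moved in both directions. In the growth hormone, IGF and thyroid hormone list, 6 of 33 genes rose and none fell; adjusted over the list alone, 15 rose and 1 fell. IGFBP2, a binding protein of insulin-like growth factors, rose by 3.78 ± 0.26 (adjusted p = 2.77e-04), and IGFBP7 by 2.22 ± 0.24. SOCS2, a feedback inhibitor of growth hormone signalling, and the thyroid hormone inactivating enzyme DIO3 had proliferative means below background and rose by at least 2.54 and 3.14 (estimates 3.37 ± 0.56 and 3.22 ± 0.26). IGF1 lay below the background level, and IGF2 had means of 4.63 and 4.70 in hypertrophic and proliferative cells, against a background level of 4.72. The list's adjusted p = 0.00222, or adjusted p = 0.460 with an estimated correlation, and 4 members rose with arrays 3 and 4 averaged, IGFBP2, IGFBP7 and DIO3 among them, while SOCS2 did not pass (adjusted p = 0.0716). Without hypertrophic array 1, 13 members rose, and 5 when any 1 of the others was left out. In Hedgehog and PTHrP signalling, 3 of 19 genes fell, the receptor PTCH1 by 1.35 ± 0.33, DISP1 by 1.34 ± 0.22 and GLI2 by 0.90 ± 0.20, with the same count adjusted over the list alone. That list's adjusted p = 0.0172, or adjusted p = 0.499 with an estimated correlation, and DISP1 passed with arrays 3 and 4 averaged, while PTCH1 and GLI2 did not (adjusted p = 0.104 and 0.0984). From 1 to 5 of its genes fell when 1 array was left out, the most without hypertrophic array 1. PTCH1 and GLI2 missed the threshold in 6 and 4 of the 8 fits that leave out 1 array (adjusted p up to 0.0918 and 0.0736).

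Among 20 chondrocyte transcription factors and receptors, 2 rose and 5 fell (adjusted p = 0.199), and adjusted over the list alone 2 rose and 6 fell. The receptor FGFR2 rose by 3.13 ± 0.24 and FGFR1 by 1.39 ± 0.22, while NFATC2 fell by 1.75 ± 0.31. SOX9 and FGFR3 differed by -0.02 ± 0.19 and 0.24 ± 0.20, neither past the test. In BMP and TGF-beta signalling, 8 of 41 rose and 5 fell (adjusted p = 0.468; 11 and 8 adjusted over the list alone), with TGFB2 higher by 2.47 ± 0.41, BMP7, below background in proliferative cells, by at least 1.76 (estimate 1.92 ± 0.44), and the BMP antagonist NOG lower, at -1.51 ± 0.16. In Wnt signalling, 6 of 44 rose and 4 fell (adjusted p = 0.928; 10 and 10 adjusted over the list alone), and the secreted inhibitors WIF1 and NOTUM rose by 3.89 ± 0.72 and 2.29 ± 0.21. Averaged arrays 3 and 4 gave 1 rise and 2 falls among the transcription factors and receptors; 1 gene rose and 1 fell in BMP and TGF-beta signalling, and 3 rose and none fell in Wnt signalling. FGFR1, TGFB2, BMP7 and WIF1 did not pass in that setting (adjusted p = 0.0637, 0.0790, 0.172 and 0.0851). Leaving out 1 array gave 2 or 3 lower among the transcription factors and receptors, 4 to 11 higher and 3 to 5 lower in BMP and TGF-beta signalling, and 4 to 8 higher and 0 to 4 lower in Wnt signalling, with the most higher in both without hypertrophic array 1. BMP7 missed the threshold in 7 of the 8 fits that leave out 1 array (adjusted p up to 0.0879).

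Markers of other cell types were partly higher on hypertrophic arrays. Of 27 endothelial markers 6 rose and none fell (adjusted p = 0.0280, or adjusted p = 0.499 with an estimated correlation), and adjusted over the list alone 8 rose and 1 fell; TEK rose by 1.33 ± 0.18, and FLT1, below background in proliferative cells, by at least 0.55 (estimate 1.28 ± 0.17). The endothelial call was lost without proliferative array 1 or without hypertrophic array 1 (adjusted p = 0.0777 and 0.0683). Of 37 leukocyte markers 6 rose and 1 fell (adjusted p = 0.0132, or adjusted p = 0.499 with an estimated correlation), with 10 and 2 adjusted over the list alone; LAPTM5 rose by 2.96 ± 0.32. With arrays 3 and 4 averaged, 3 endothelial, 3 leukocyte and 1 osteoclast marker rose and none fell. From 3 to 7 endothelial and 3 to 11 leukocyte markers rose when 1 array was left out, the most without hypertrophic array 1, where 2 leukocyte markers fell. The fewest came without proliferative array 3 or 4, and for leukocyte markers when any 1 proliferative array was left out. Of 15 osteoclast markers 3 rose and 1 fell (adjusted p = 0.138; 4 and 2 adjusted over the list alone). Besides MMP9 and ATP6V0D2, the receptor TNFRSF11A rose by 0.49 ± 0.11, and NFATC1 fell by 0.83 ± 0.15. The osteoclast protease CTSK, chosen after its values were seen, differed by 1.08 ± 0.41 (adjusted p = 0.159). TNFRSF11A missed the threshold in 5 of the 8 fits that leave out 1 array (adjusted p up to 0.0906), and with arrays 3 and 4 averaged MMP9, TNFRSF11A and NFATC1 did not pass (adjusted p = 0.0794, 0.112 and 0.0563). From 1 to 4 osteoclast markers rose when 1 array was left out, the most without hypertrophic array 1.

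Among 16 osteoblast and bone matrix markers 3 rose and none fell (adjusted p = 0.138; 6 and 2 adjusted over the list alone), and COL1A1 differed by -0.16 ± 0.37. The 3 were LOX, MEPE and COL24A1, of which MEPE is also a mineralisation gene. This list passed, in the higher direction, with arrays 3 and 4 averaged (adjusted p = 0.0393, 1 gene higher), arrays 1 and 2 alone (adjusted p = 8.87e-05), proliferative arrays 1 and 2 only (adjusted p = 0.0112) and the mean of a gene's probe sets (adjusted p = 0.0219). The rotation test fry, which asks whether a list moves one way and not whether it moves more than other genes, gave adjusted p = 0.0284. Among 15 erythroid markers 1 rose and 1 fell (adjusted p = 0.617; 2 and 1 adjusted over the list alone), with the transferrin receptor TFRC lower, at -2.05 ± 0.26, and the globin HBA1 different by 0.76 ± 0.51 (adjusted p = 0.456). None of 27 skeletal muscle markers passed (adjusted p = 0.753). Of 28 perichondrium, tendon and fibroblast markers 5 rose and 2 fell (adjusted p = 0.145; 7 and 3 adjusted over the list alone), and of 14 adipocyte markers 2 rose and 1 fell (adjusted p = 0.928; 2 and 2 adjusted over the list alone), with ADIPOQ, below background in proliferative cells, higher by at least 2.17 (estimate 2.65 ± 0.40). Averaging arrays 3 and 4 left 1 erythroid marker lower, 2 fibroblast and tendon markers higher and 1 adipocyte marker higher. That marker was FABP4 (adjusted p = 0.0112), while ADIPOQ, LOX and COL24A1 did not pass then (adjusted p = 0.0553, 0.106 and 0.0784). Leaving out 1 array gave 2 to 4 osteoblast markers and 2 to 6 fibroblast and tendon markers higher, the latter the fewest without proliferative array 3 or 4 or hypertrophic array 4. With arrays 1 and 2 alone the fibroblast and tendon list passed (adjusted p = 0.0413). HINTW, a gene of the female-specific W chromosome of birds, read 11.95 and 12.1 on proliferative arrays 1 and 2, 4.00 and 4.26 on proliferative arrays 3 and 4, and 10.9 to 12.4 on hypertrophic arrays (adjusted p = 0.327). Against proliferative arrays 1 and 2 alone, 193 genes were higher and 116 lower.

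Ribosomal protein genes had a median of 0.13, and the list passed camera (adjusted p = 0.00445, or adjusted p = 0.506 with an estimated correlation). Its 2 members that passed among 68 were RPL39L, higher by 0.47 ± 0.10, and RPS19BP1, at -0.69 ± 0.12, which is a binding protein of a ribosomal protein. The list did not pass with arrays 1 and 2 alone (adjusted p = 0.590). Neither gene passed with arrays 3 and 4 averaged, and RPL39L missed the threshold in 6 of the 8 fits that leave out 1 array (adjusted p up to 0.0704). Integrins, adhesion and cytoskeleton had 11 of 48 genes higher and 3 lower (adjusted p = 0.0795; 13 and 7 adjusted over the list alone), with CDH2, below background in proliferative cells, higher by at least 0.77 (estimate 1.75 ± 0.16) and THBS1 lower, at -2.08 ± 0.30. Limb patterning genes had 4 of 29 lower and none higher (adjusted p = 0.105; also 4 adjusted over the list alone), led by SHOX at -1.90 ± 0.16 and HOXA11 at -1.50 ± 0.19. Glycolysis and hypoxia had 8 of 39 higher and 7 lower (adjusted p = 0.916; 12 and 10 adjusted over the list alone), with NDRG1 at 3.56 ± 0.58 and ADM at 2.79 ± 0.61; ADM missed the threshold in 6 of the 8 fits that leave out 1 array (adjusted p up to 0.0764). Matrix proteases had 5 of 45 higher and 7 lower (adjusted p = 0.857; 10 and 10 adjusted over the list alone), and articular zone markers 4 of 17 higher and 2 lower (adjusted p = 0.400; 6 and 5 adjusted over the list alone). Higher and lower counts with arrays 3 and 4 averaged were 4 and 1 for integrins, adhesion and cytoskeleton, 0 and 2 for limb patterning, 0 and 2 for glycolysis and hypoxia, 0 and 2 for matrix proteases and 2 and 2 for articular zone markers. NDRG1 and ADM did not pass in that setting (adjusted p = 0.0798 and 0.154). Leaving out 1 array gave 4 to 12 higher for integrins, 2 to 4 lower for limb patterning, 2 to 11 higher and 2 to 8 lower for glycolysis and hypoxia, 1 to 11 higher and 2 to 9 lower for matrix proteases and 0 to 4 ribosomal protein genes higher, in each the most without hypertrophic array 1. The integrin list passed without hypertrophic array 2 (adjusted p = 0.0401), and limb patterning passed without proliferative array 3 (adjusted p = 0.0433), with dim probe sets dropped (adjusted p = 0.0259) and with proliferative arrays 1 and 2 only (adjusted p = 0.0176). In the lists of matrix proteases and of glycolysis and hypoxia the mean was above 0, at 0.28 and 0.32, while the median was below it, at -0.02 and -0.06.

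Higher and lower counts were 6 and 3 of 50 for apoptosis and autophagy (9 and 6 adjusted over the list alone), 5 and 4 of 42 for ion and water transport (also 5 and 4), 2 and 6 of 41 for lipid metabolism (3 and 10), and 2 and 1 of 18 for the circadian clock (also 2 and 1), with camera adjusted p = 0.732, 0.686, 0.225 and 0.484. The water channel AQP1, below background in proliferative cells, rose by at least 2.59 (estimate 2.88 ± 0.28). Immediate early genes had 1 of 33 higher, DUSP4, and 1 lower, MYC at -1.48 ± 0.22 (adjusted p = 0.484; the same counts adjusted over the list alone). Oxidative phosphorylation had 2 of 78 higher (0 adjusted over the list alone). These were ATP5S and NDUFAF8, which the start of their symbols alone placed in the list. The proteasome had 1 of 30 higher and 1 lower, histones 1 of 11 higher and 1 lower, and heat shock proteins 2 of 62 higher and 4 lower. In the last 3 the counts adjusted over the list alone were the same. Camera gave adjusted p = 0.916, 0.928, 0.759 and 0.686, in that order. Averaging arrays 3 and 4 left 3 genes higher and 1 lower in apoptosis and autophagy, 2 and 1 in ion and water transport, 1 and 0 in lipid metabolism, and 0 and 1 among immediate early genes, where DUSP4 did not pass (adjusted p = 0.0896). Without hypertrophic array 1, higher counts were 11 for apoptosis and autophagy, 10 for ion and water transport, 5 for lipid metabolism, 4 for immediate early genes and 7 for oxidative phosphorylation. The lowest higher counts when another array was left out were 3, 4, 1, 1 and 0. Lower counts for lipid metabolism ran from 1 without proliferative array 3 to 8 without hypertrophic array 1. No gene of the circadian clock, oxidative phosphorylation, proteasome, histone and heat shock lists passed with arrays 3 and 4 averaged. Immediate early genes passed as a list, lower, with arrays 3 and 4 averaged (adjusted p = 0.0397) and with arrays 1 and 2 alone (adjusted p = 3.70e-09), and higher with arrays 3 and 4 alone (adjusted p = 5.47e-04), whose spread may be technical. Heat shock proteins passed with arrays 1 and 2 alone (adjusted p = 0.0233). Leaving out 1 array gave 0 to 4 heat shock genes higher and 2 to 6 lower.

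In all, 12 of 37 lists passed camera at the preset correlation and 0 with an estimated correlation, while 18 passed the rotation test fry, which compares no list with other genes. The adjusted p of 0.499 that many lists share is a tie made by the adjustment. Unadjusted, camera with an estimated correlation gave these lists p from 0.0707 (G2 and mitosis) to 0.189 (endothelial markers). The 3' minus 5' difference of the actin controls, a sign of RNA integrity, was 1.21 ± 0.32 on hypertrophic and 1.38 ± 0.54 on proliferative arrays (SD, n = 4; exact permutation p = 0.6, 0.743 after adjustment over 3 controls), and averaged 1.65 on arrays 1 and 2 of both groups against 0.94 on arrays 3 and 4. That of GAPDH was -0.33 ± 0.18 and -0.45 ± 0.082 (exact permutation p = 0.229, 0.686 after adjustment) and that of EF1a 0.30 ± 0.11 and 0.29 ± 0.096 (exact permutation p = 0.743, the same after adjustment). Both were highest on hypertrophic array 1, at -0.0592 and 0.413.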

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

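Tests of the second HINTW probe set, of repeat hybridisation, of a single mixing share, of RNA degradation and of splits with arrays 3 and 4 averaged were chosen only after the results they concern had been seen.

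All 18 results listed here had 1 array far from the other 3 of its group, among 310 groups of 4 examined. For 4 independent arrays chance alone gives about 1 in 20. With arrays 3 and 4 of a group nearly identical, array 1 or 2 is flagged more often than that. The flags are therefore not shown to exceed chance. The ratio after each gene is the gap to the nearest array divided by the range of the group. Proliferative array 1 was low in EFEMP1 (0.857), FGFR1 (0.849), MEPE (0.892), CD74 (0.940) and ALPL (0.861), with values of 5.10, 7.02, 5.70, 6.31 and 8.51. Proliferative array 2 was low in THBS1 (0.887, at 10.6) and high in VEGFA (0.908, at 7.02), and proliferative array 4 was low in SOX18 (0.944, at 4.59). Hypertrophic array 1 was low in EFEMP1 (0.891, at 10.6), TNFSF10 (0.895, at 7.76), DIO3 (0.850, at 6.98), ATG10 (0.871, at 5.18), LAPTM5 (0.898, at 6.95) and MATN1 (0.936, at 11.3), and high in TPM3 (0.841, at 11.3). Hypertrophic array 2 was high in UHRF1 (0.874, at 5.54) and low in SCD (0.994, at 7.26) and IGF1 (0.858, at 3.05), the latter below the background level.

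Hypertrophic array 1 lay between the groups on the first component, and without it 2503 genes passed in place of 1683. Among 281 genes that were at least 4-fold higher in the other hypertrophic arrays, only 8.19% reached the mean of the other 3 on array 1. It was 28.2% to 78.9% when each other hypertrophic array was left out in the same way. Those values are no clean baseline. Their reference mean includes the low array 1 and, for arrays 3 and 4, the nearly identical partner. Proliferative cells in hypertrophic array 1 may account for its 8.19%, which was within the limit set beforehand for such a mixture. But the 406 genes at least 2-fold lower would need a median share of 27.8% of such cells (quartiles 7.01% and 47.5%). The rising genes would need one of 82.5% (quartiles 63.3% and 92.8%), so 1 share does not serve both on this measure. The 2 sets differ in their size limit. On hypertrophic array 2 the rising genes also had the higher median, 25.7% against 7.55%, but on hypertrophic arrays 3 and 4 the lower. These shares, too, rest on references that include hypertrophic array 1. The gap may lie partly in the measure, and a mixture is not excluded. RNA degradation as the cause stays open: the actin 3' minus 5' difference of 1.58 is below those of proliferative arrays 1 and 2 (1.90 and 1.80), but the differences of GAPDH, at -0.0592, and EF1a, at 0.413, were the highest of the 8 arrays (others up to -0.336 and 0.402). A different stage of hypertrophy in that pool stays open and was not tested.

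Arrays 3 and 4 of each group may be repeat hybridisations of 1 pool. The correlation of their differences between probe sets of a gene was 0.209 at most, against 0.480 to 0.775 for the other pairs within a group, as shared RNA with separate labelling might give. If so, the averaged fit with 261 genes higher and 161 lower counts each pool once. The labels do not say which pool each array came from, so no biological explanation was tested.

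HINTW read near background on proliferative arrays 3 and 4. A failed probe set is opposed by the second HINTW probe set, whose log2 difference between arrays 3 and 4 and arrays 1 and 2 was -1.43. Pools with few or no female chicks are a candidate explanation, under which Z-linked genes should be higher on those arrays. The median difference of 61 Z-linked genes was 0.0021, at the 67.3th percentile of 10000 lists matched on expression (95% of them between -0.09 and 0.06); on hypertrophic arrays, where HINTW was lower on 3 and 4, it was 0.10, at the 99.0th percentile. The test leaves this open, because the share of females behind arrays 1 and 2 is unknown. If such pools were used, the sex of the chicks also differed between proliferative arrays 3 and 4 and the hypertrophic arrays.

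Of 35 splits of the 8 arrays into 4 and 4, only 1, the real one, gave as many as 3368 probe sets past the threshold, and the highest other count was 33, in the split of arrays 1 and 2 against arrays 3 and 4. These splits treat arrays 3 and 4 of a group as separate samples, which they may not be, so they do not settle the question. With those arrays averaged, the real split gave 755 probe sets and the highest other 0, but 10 splits are too few for a share under 0.05.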

How the results depend on the processing

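Settings that average, drop or split arrays 3 and 4, or use proliferative arrays 1 and 2 only, were chosen after seeing the data. Of 131 named genes past the threshold, 62 passed with arrays 3 and 4 averaged, and 41 lost the call when at least 1 array was left out. Counts follow in the order probe sets higher, probe sets lower, genes higher, genes lower, genes at least 2-fold higher and genes at least 2-fold lower, from 1726, 1642, 955, 728, 545 and 319. Arrays 3 and 4 averaged gave 428, 327, 261, 161, 221 and 125, arrays 1 and 2 only 486, 683, 309, 278 and 307, with genes at least 2-fold lower within 1.5 times, and proliferative arrays 1 and 2 only 301, 279, 193, 116, 179 and 101. Arrays 3 and 4 only gave 4909, 5033, 2356, 2211, 1078 and 704 from as many arrays as arrays 1 and 2 only, so the number of arrays alone does not account for the counts. If arrays 3 and 4 are repeats of 1 pool, calls from these arrays only set single pools against technical spread. Arrays 1 and 2 against 3 and 4 as a block gave 2680 and 2853 probe sets and 1197 genes lower, and COL9A1, MATN1, IBSP, TOP2A and CDKN1A passed there (adjusted p = 0.0425, 0.0287, 0.00878, 0.0116 and 0.0177) but not with averaging (0.270, 0.254, 0.138, 0.283 and 0.265). A plain two-sample test gave 565, 509, 349, 233, 218 and 127, and array weights gave 3945, 3811, 1973, 1694, 893 and 521. A test against a minimum log2 change of 1 (treat), stricter by construction, gave 73, 12, 49, 8, 49 and 8. Leaving out 1 array gave 831 to 2987, 677 to 2048, 484 to 1562, 301 to 941, 355 to 841 and 197 to 406; the lowest counts came without proliferative array 3 or 4 and the highest without hypertrophic array 1, and the share of the first component ran from 47.4% without hypertrophic array 4 to 61.8% without hypertrophic array 1. Of the genes past the threshold 56.7% were higher, and 48.4% with arrays centred on ribosomal proteins. That centring subtracts the mean difference of the ribosomal proteins from every gene. With it 1620 probe sets and 898 genes were higher and 2217 and 958 lower.

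The cartilage matrix list lost its call with ribosomal centring (adjusted p = 0.0527), an estimated correlation (0.665), fry, which asks another question (0.131), averaging (0.0743), arrays 1 and 2 only (0.796) and proliferative arrays 1 and 2 only (0.118). With an estimated correlation 0 lists passed, and the lists of hypertrophic markers and of G2 and mitosis had adjusted p = 0.499. S phase passed with arrays 3 and 4 only (adjusted p = 0.00226), a p that may rest on technical spread, as may the lost call of the endothelial list there (0.0521), and S phase ranged from 0.0197 without hypertrophic array 1 to 0.294 without hypertrophic array 3. The immediate early list, which did not pass with 8 arrays (adjusted p = 0.484), was lower with arrays 1 and 2 only (3.70e-09) and with averaging (0.0397), and higher with arrays 3 and 4 only (5.47e-04). Arrays 1 and 2 only also ended the calls of glycosaminoglycan synthesis (0.211), collagen processing (0.0605) and ribosomal proteins (0.590). The cause was not tested. Among other probe sets of genes named by the rule, 54 had the same sign but did not pass where the representing probe set did. Other probe sets of 12 genes named by the rule and past the threshold had the opposite sign: KCNK2 -0.056, COL6A3 -0.12, CENPN 0.0023, SMAD7 -0.20, CHST12 0.026, PIEZO2 -0.12, DUSP4 -0.12, FBXL21 -0.049, TNFRSF11A -0.095, FLT1 -0.063, RHCE -0.033 and FBN1 -0.044. None of these 12 probe sets passed (limma adjusted p from 0.480 to 0.995). Their means over the 8 arrays ran from 2.98 to 4.42, all below the background level of 4.72, so their signs say little about these genes.

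With the replicate number as a replicate block, 867 genes were higher and 684 lower. Same-numbered arrays deviated together at r = 0.153, 0.011, 0.222 and -0.009, and none was highest with its own number. This comparison cannot decide whether the numbers pair the arrays, because arrays with different numbers in a group can be nearly identical. The actin controls differed between lower and higher numbers in the same direction in both groups, so a link by number is not excluded. Genes near the background level of 4.72 limit what can be seen, since RMA compresses their differences.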

Other observations

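Several further genes with large rises are named here after their values were seen. FKBP5, a chaperone of steroid receptors, rose by 3.40 ± 0.27 (log2 difference ± SE, n = 4 per group, limma adjusted p = 3.77e-04), with 9.86 to 10.4 on hypertrophic and 6.25 to 7.53 on proliferative arrays. Glutamine synthetase, GLUL, and PIK3IP1, below background in proliferative cells, rose by at least 3.44 and 3.68 (estimates 3.59 ± 0.71 and 3.88 ± 0.62). The extracellular superoxide dismutase SOD3 rose by 3.68 ± 0.68, the receptor accessory protein RAMP2 by 3.39 ± 0.27, the prostaglandin synthase PTGDS by 4.16 ± 0.59 and the lipocalin EXFABP by 3.99 ± 0.92. PDK4, a kinase that limits glucose oxidation, differed by 2.68 ± 0.99 (adjusted p = 0.141), SGK1 by -0.31 ± 0.49 and KLF9 by 0.19 ± 0.55.

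A wider glucocorticoid or fasting response may lie behind the rise of FKBP5. The test used 21 further response genes, chosen before their values were examined as a set, of which the fixed lists also hold 10. MAOA, below background in proliferative cells, rose by at least 0.78 (estimate 1.02 ± 0.18) and SESN1 by 2.99 ± 0.58, none fell, and their median log2 difference was 0.076, at the 88.4th percentile of 10000 lists matched on expression (95% between -0.20 and 0.15). The test decided neither way.

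A probe set for a viral sequence was the only 1 of 742 viral and reporter probe sets past the threshold. It read 4.29, 6.41, 4.93 and 4.72 on proliferative arrays 1 to 4 and 6.80, 8.28, 9.04 and 9.21 on hypertrophic arrays 1 to 4 (difference 3.25 ± 0.59, adjusted p = 0.0125).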
